A study of Mus musculus with 5 samples.

How the data were processed

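Spleens of Sirt6 knockout mice (2 arrays) and of Sirt6 knockout mice heterozygous for Rela (3 arrays) were each hybridised on a 2-colour array, with 15 ug of amplified RNA per dye, against wild-type spleen RNA from a pool. Per the labels the mutant RNA carried Cy5 and the pool Cy3 on all 5 arrays, and the dyes were not swapped. Only the deposited table of processed values was used. The values deposited by the authors were read as log2 ratios of Cy5 over Cy3. The base follows from their range (-9.12 to 8.27, about symmetric around 0) and from the custom of the source database, and neither the base nor the direction nor the normalization is given in the sources used here. The deposited column medians were 0.004 and -0.006 on the knockout arrays and 0.004, -0.039 and -0.014 on the heterozygous arrays. Cells left blank by the authors follow a filter whose rule is not given in the sources used here. Spot intensities and raw images were not analysed here.

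The table held 38784 spots, of which 17744 had a value on all arrays and 11338 on none. Spots with a value numbered 22274 and 22851 on the knockout arrays and 19768, 22871 and 21838 on the heterozygous arrays. The gene annotation named 1 gene for 22204 probes and several for 0 probes, and left 16580 unnamed here. A table of mouse genes from assembly GRCm38.p6 served only for names. Each array was centred on its median, spots of a probe were averaged, and then probes naming the same gene were averaged, which was the case for 4955 of 14654 symbols with more than 1 probe. The 9000 genes with a value on all 5 arrays were tested. The SD of gene values was 0.94 and 1.12 on the knockout arrays and 1.29, 0.76 and 0.97 on the heterozygous arrays.

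All 5 arrays were fitted at once with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each group, so that the groups shared their estimate of spread (3 residual and 3.63 prior degrees of freedom). The tests were the mean of the knockout group against 0, the mean of the heterozygous group against 0, and the heterozygous minus the knockout mean. They were 2-sided, with the Benjamini-Hochberg method at 0.05 over all genes tested. A value marked SE is limma's moderated standard error, from the spread of all 5 arrays and the prior. The n beside it counts the arrays in the mean, so the SE is not the spread of those arrays alone. The pool counts as 1 control sample, so a test against it leaves out the spread between wild-type spleens, and a dye bias stays in it. Pool and dye cancel in the difference between the groups. The series describes its samples as biological replicates and does not identify the animals further, so the p-values measure only the spread between these samples.

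Gene lists, 34 in number with 1036 symbols, were written from general knowledge. Of these symbols 879 were on the array, 39 of them under a renamed symbol, and 746 list memberships were tested. Each list was tested with limma's camera (preset correlation of 0.01), with the Benjamini-Hochberg method over the lists within a comparison. Camera with the correlation estimated from the data, and fry, were run beside it. Fry tests whether the members change on balance in 1 direction, and its mixed form whether they change in either direction. Members were also called with the adjustment made over the list alone. For the question of attenuation, the 5% highest and 5% lowest genes on 1 knockout array were read on the other knockout array and on the heterozygous arrays. The share of genes on 1 side of the pool was set against independent arrays and against unchanged spleens simulated with a shared pool that varies like a spleen, the latter added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

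The lists, tests, thresholds, most alternatives and the rule for naming genes were chosen before the data were examined. Sirt6 and Rela were always named. In each comparison the rule named the 8 genes with the largest rise and the 8 with the largest fall past the threshold that lay the same way on every array of the group, or did not overlap between groups. Where fewer passed, the genes of smallest unadjusted p that met the same condition filled the places and are said not to have passed. From each list described, up to 4 members with the largest absolute moderated t were named. A few genes among these were left out for length. The alternatives were the values as deposited, quantile normalization, scaling to the same median absolute deviation, genes with a value on at least 2 arrays of each group, each probe on its own, the least variable 25% of genes left out, only the arrays of the group, robust eBayes, the replicate number as a block, and each array left out in turn. An array left alone in its group was assumed to vary like the others. Leaving out heterozygous arrays 1 and 3 together was added after the data were seen.

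The fits were tested on simulated data with 9000 genes, in which 50 genes at each size of change were altered. At log2 changes of 1, 2, 4 and 6, limma recovered 2%, 24%, 90% and 90% in the knockout group, 2%, 52%, 98% and 100% in the heterozygous group, and 0%, 4%, 62% and 92% in the difference. False calls made up 7.21%, 4.55% and 10.2% of the calls. A shift of 1 in 43 genes was called by camera in each comparison (adjusted p = 4.02e-23, 2.13e-28 and 3.46e-13), and 0 unchanged lists were called. The simulated genes and arrays were drawn independently, without correlation within lists and without a shared pool. These rates therefore do not cover the effect of either on the real data.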

Results

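Gene expression in mouse spleen was measured on 5 2-colour microarrays, each with mutant spleen RNA labelled with Cy5 and RNA of a wild-type spleen pool labelled with Cy3. The Sirt6 knockout group had 2 arrays. The other group had 3 arrays of Sirt6 knockout spleens that were also heterozygous for Rela. Sirt6 encodes a chromatin-bound deacetylase of the sirtuin family, and Rela encodes the p65 subunit of the transcription factor NF-kB. The design asks how the spleen of Sirt6 knockout mice differs from wild type, and whether losing 1 copy of Rela moves those differences back towards wild type. Of 38784 spots, between 19768 and 22871 had a value on an array, and 9000 genes with a value on all 5 arrays were tested. Values are read as log2 ratios to the pool, above 0 where the mutant spleen was brighter, though the log base and the direction are not given in the sources used here. No wild-type spleen was hybridised apart from the pool, so a comparison with the pool leaves out the spread between wild-type spleens. The dyes were not swapped, so a dye bias of a probe stays in it. Both cancel in the difference between the mutant groups. The measured Y-linked genes lay above the pool on all 5 arrays. A difference in sex between spleens and pool therefore cannot be told apart from genotype in the comparisons with the pool. The number of arrays, 2 and 3, limits the precision of every value.

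The targeted genes came first, as a check of the labels. Sirt6 had 2 probes, of which probe 4451 had no value on any array and probe 9711 had a single value, -4.31 on heterozygous array 2, so the knockout could not be checked. Rela, with 1 probe, lay at 0.48 and 1.07 on the knockout arrays. It lay at -0.084 and -0.20 on heterozygous arrays 2 and 3, and at 1.15 on the library labelled heterozygous 1, which is the level of the knockout arrays. The mean difference of Rela between the groups was -0.49 ± 0.56 (SE, n = 3 and 2, limma adjusted p = 0.858). Without the library labelled heterozygous 1 it was -0.92 (limma adjusted p = 0.354). Whether the Rela probe lies in the deleted part of the gene is not given in the sources used here.

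Across genes, which are not independent replicates, the 2 knockout arrays correlated at r = 0.82. The heterozygous arrays did not form such a group. Arrays 1 and 2 correlated at 0.34, arrays 1 and 3 at 0.21 and arrays 2 and 3 at -0.01. Array 3 correlated at -0.16 and -0.02 with the knockout arrays, while array 1 correlated at 0.39 and 0.59 and array 2 at 0.46 and 0.38 with knockout arrays 1 and 2. Unchanged spleens simulated against 1 shared pool, taken to vary like a spleen, gave r between 0.481 and 0.506 and a mean covariance of 0.626. These figures follow from the spread assumed for the pool. A pool that varies less would give lower ones, and a pool that varies more would give higher ones. Values above or below them therefore do not show more or less agreement than a shared pool gives. The knockout arrays had a covariance of 0.865, above the simulated mean, as had knockout array 2 with the library labelled heterozygous 1 (0.846). Heterozygous arrays 2 and 3 had one of -0.00456. All arrays share the pool and the dye orientation, so agreement between arrays includes what these add.

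The Sirt6 knockout spleens had low levels of red cell and cell division transcripts and high levels of glucocorticoid-responsive, neutrophil and immediate early transcripts relative to the pool, by the medians of their lists. All 38 measured erythroid genes lay below the pool in their mean, with a median log2 ratio of -2.36. The examples were Epb42 at -5.30 ± 0.93 (SE, n = 2), Trim10 at -4.67 ± 0.84, Sptb at -3.62 ± 0.63 and Xk at -2.48 ± 0.41. Epb42 and Sptb encode proteins of the red cell membrane skeleton, and Xk encodes a red cell membrane protein. Limma called 27 of these genes lower when adjusted over the list alone and 0 over all genes tested. All 47 cell cycle genes also lay below the pool (median -1.82), and 32 were called lower when adjusted over the list alone, 0 over all genes. Cdc6, which loads the replicative helicase onto DNA, was at -2.77 ± 0.56, its helicase subunit Mcm7 at -2.08 ± 0.49, the replication-coupled methylation factor Uhrf1 at -2.26 ± 0.43 and the kinetochore motor Cenpe at -2.08 ± 0.41. Camera, which sets a list against all other genes, called both lists (adjusted p = 2.08e-16 and 1.59e-15). Neither call held when the correlation between genes was estimated (adjusted p = 0.576 with an estimated correlation for both). That estimate takes in the spread of the heterozygous arrays as well. The SD of the erythroid array medians was 0.0016 in the knockout and 1.37 in the heterozygous group. For cell cycle genes it was 0.24 and 1.28.

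Glucocorticoid-responsive genes lay above the pool in 20 of 22 members, with a median of 1.85, and 14 were called higher when adjusted over the list alone (0 over all genes). They included the transcription factor Klf9 (2.70 ± 0.35, SE, n = 2), the MAP kinase phosphatase Dusp1 (3.09 ± 0.40), the receptor inhibitor Errfi1 (3.38 ± 0.52) and the interleukin decoy receptor Il1r2 (3.04 ± 0.50). Of 18 immediate early genes, 10 were called higher and 1 lower when adjusted over the list alone, among them Ier3 (2.71 ± 0.42), Junb (1.67 ± 0.44) and Fos (4.21 ± 1.11). Camera called both lists higher (adjusted p = 9.68e-11 and 0.00142), with adjusted p = 0.576 with an estimated correlation for both. The growth hormone and insulin-like growth factor list had a median of 1.47, with 6 genes called higher and 1 lower over the list alone. Igfbp4 (1.53 ± 0.32), the growth hormone signalling inhibitor Socs2 (1.70 ± 0.35) and the insulin receptor substrate Irs1 (1.47 ± 0.32) were above the pool, and the binding protein Igfbp2 was below it at -4.13 ± 0.57. The camera adjusted p of this list was 0.00628, against an adjusted p of 0.576 with an estimated correlation. On knockout arrays 1 and 2 the medians were 0.87 and 1.61 for immediate early genes and 0.83 and 1.31 for the growth factor list. The latter was the only list past fry, a test of the members alone, in this comparison (fry adjusted p = 0.0354).

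Markers of immune cell types lay on both sides of the pool. Neutrophil and granule genes had a median of 1.15, with 8 of 23 called higher over the list alone. The antimicrobial peptide gene Camp was at 2.92 ± 0.42 (SE, n = 2), S100a9 at 2.88 ± 0.53, the protease inhibitor Stfa3 at 3.76 ± 0.83 and Mmp9 at 1.70 ± 0.41. Macrophage and monocyte markers had a median of 0.98, with 3 of 25 called higher, such as the adhesion molecule Vcam1 (2.73 ± 0.35) and the iron exporter Slc40a1 (1.96 ± 0.35). B cell markers had a median of -1.03, and 3 of 21 were called lower over the list alone, Vpreb3 (-2.30 ± 0.35), Fcrla (-1.92 ± 0.43) and the follicle-homing receptor Cxcr5 (-1.97 ± 0.44). Natural killer cell markers had a median of -0.82, with 3 of 15 called lower, among them the lectin receptor Klre1 (-3.02 ± 0.48) and granzyme A, Gzma (-1.89 ± 0.34). Interferon-stimulated genes had a median of -0.88 and 11 of 32 called lower, led by Usp18 (-2.69 ± 0.41), Oasl1 (-2.70 ± 0.44), Oas1g (-3.01 ± 0.52) and Ifit3 (-2.19 ± 0.40). On knockout arrays 1 and 2 the medians were 1.79 and 0.60 for neutrophil, 0.99 and 0.54 for macrophage and -0.54 and -1.11 for natural killer cell genes. T cell markers, 12 above and 12 below, had a median of 0.00 and a camera adjusted p of 0.770. Camera called the neutrophil, macrophage, B cell, natural killer and interferon lists (adjusted p = 2.22e-05, 0.00628, 7.25e-07, 0.00783 and 2.74e-07). With an estimated correlation the adjusted p was 0.576 for the neutrophil, B cell and interferon lists and 0.673 for the macrophage and natural killer lists. The macrophage call was also lost without knockout array 1 (camera adjusted p = 0.164).

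NF-kB target genes went both ways in the knockout. Of 43 measured, 22 lay above the pool and 21 below, with a median of 0.06 and a camera adjusted p of 0.199. Over the list alone 7 were called higher and 2 lower. Nfkbib, which encodes an inhibitor of NF-kB, was at 2.62 ± 0.33 (SE, n = 2), Vcam1 at 2.73 ± 0.35 and Ier3 at 2.71 ± 0.42, while Tnfaip2 was at -2.17 ± 0.39. The fry test for members changing in either direction gave an adjusted p of 0.00900 for this list, and 17 of 34 lists passed it in this comparison. For NF-kB target genes it gave 0.248 in the heterozygous group and 0.246 in the difference between the groups.

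Genes of the exocrine pancreas, which lies against the spleen, were the lowest list on the knockout arrays (median -2.74, 9 of 12 called lower over the list alone). Zymogen granule genes Gp2 and Zg16 were at -5.11 ± 1.07 and -2.77 ± 0.51 (SE, n = 2), Rnase1 at -2.49 ± 0.48 and chymotrypsinogen, Ctrb1, at -2.18 ± 0.42. Core histone genes had a median of -1.50, with 15 of 25 called lower and 2 higher over the list alone, but array medians of -0.80 and -2.28 on knockout arrays 1 and 2. H2bc3 was at -3.16 ± 0.68 and H4c14 at -3.07 ± 0.67. Histone genes are near-identical in sequence, so a probe for 1 of them can bind others. Ribosomal protein genes had a median of 0.62, with 9 called higher, such as Rps28 (1.91 ± 0.36) and Rps29 (1.47 ± 0.31), and 3 lower, such as Rpl13a (-1.50 ± 0.34). Camera called these 3 lists (adjusted p = 1.33e-06, 7.99e-06 and 7.35e-05, each with adjusted p = 0.576 with an estimated correlation). Endothelial genes had a median of 0.81 and DNA repair genes one of -0.52, with 0 members past the list alone. Examples are the endothelial receptor Robo4 (2.14 ± 0.48) and cadherin Cdh5 (1.45 ± 0.39), and the repair genes Xrcc6 (-1.85 ± 0.39) and Exo1 (-1.86 ± 0.43). Their camera adjusted p values were 0.00118 and 0.00142, with an adjusted p of 0.576 with an estimated correlation for both. Camera also called oxidative phosphorylation (median -0.35, Cycs at -0.94 ± 0.34) and the unfolded protein response and heat shock (median -0.52, Dnaja1 at -1.69 ± 0.58). The first had medians of -0.18 and -0.57 on knockout arrays 1 and 2. Both had a camera adjusted p of 0.0483 and 0 members past the list alone, and their adjusted p with an estimated correlation was 0.784 and 0.576. Without knockout array 2 the first had an adjusted p of 0.364, and without knockout array 1 the second had one of 0.164. Both calls were also lost without heterozygous array 3 (0.0643 and 0.0766), and the first without heterozygous array 2 (0.0540).

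Gene by gene, limma called 0 of 9000 genes in the knockout group against the pool, with a smallest adjusted p of 0.0912. At an unadjusted p under 0.05 there were 1835 genes (884 higher, 951 lower). Chance gives 450 only if the pool equals the wild-type mean, since the pool's own deviation is not in the test. The excess over 450 therefore includes what sets the pool apart. Both arrays lay on 1 side of the pool for 81.5% of genes, against 50% by chance for independent arrays. Unchanged spleens simulated against a shared pool, taken to vary like a spleen, gave 66.2%. That share follows from the spread assumed for the pool, and a pool that varies more would give a higher one. The gap therefore does not show agreement beyond that of a shared pool. The genes with the smallest p, none past the threshold and all at an adjusted p of 0.0912, included Bmper, a binder of bone morphogenetic proteins (3.01 ± 0.34, SE, n = 2), the acyl-CoA dehydrogenase gene Acadsb (3.21 ± 0.39), the Y-linked gene Uty (2.70 ± 0.33) and the growth factor receptor Pdgfra (2.96 ± 0.37). On the other side were the ligand Wnt10a (-3.17 ± 0.39), Abhd2 (-2.70 ± 0.37), Zfp473 (-2.47 ± 0.34), Ecrg4 (-2.57 ± 0.36), eosinophil peroxidase, Epx (-3.11 ± 0.44), thioredoxin, Txn1 (-3.54 ± 0.51) and Mbd2 (-3.12 ± 0.43), 1 of whose probes read 0.17. With the spread taken from the 2 knockout arrays alone, limma called 3321 genes (1564 higher, 1757 lower), and with the least variable 25% of genes left out it called 641. The unadjusted count was 693 without knockout array 1 and 446 without knockout array 2.

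**Figure D1:**
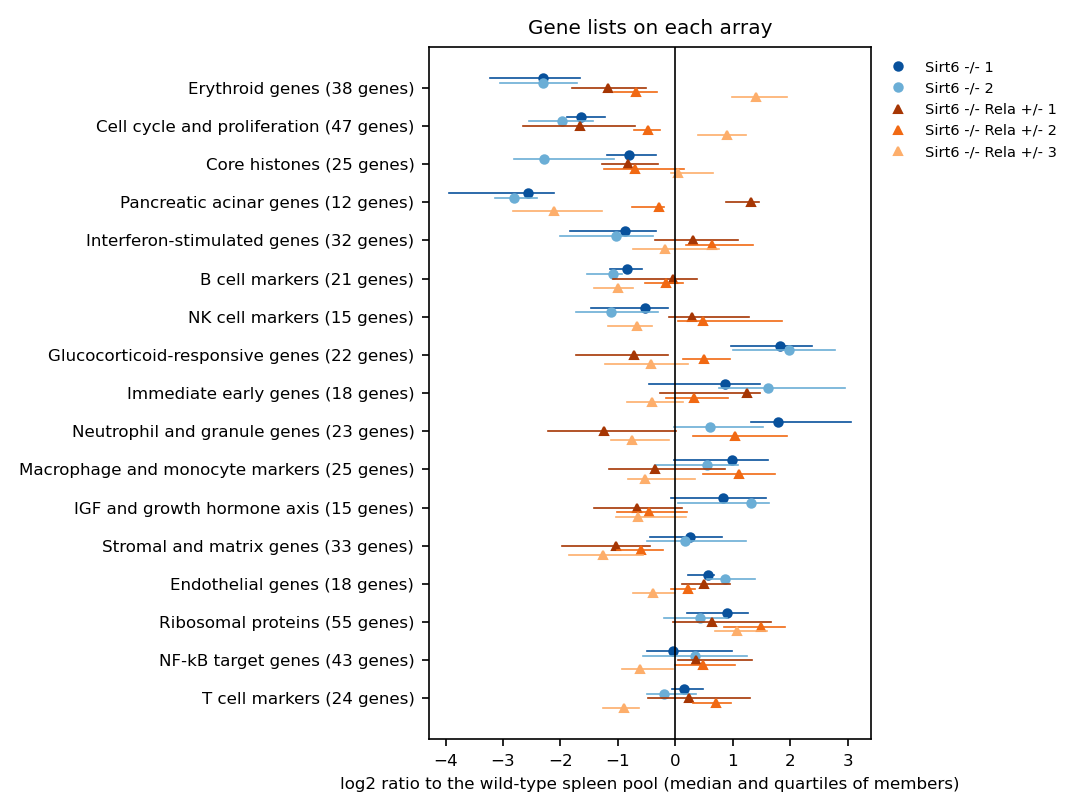
Median log2 ratio to the wild-type pool (points) and quartiles (lines) of the members of 17 gene lists on each array, with circles for the 2 Sirt6 knockout arrays and triangles for the 3 Sirt6 knockout Rela heterozygous arrays. Erythroid genes sat at -2.30 on both knockout arrays and at -1.16, -0.68 and 1.41 on heterozygous arrays 1, 2 and 3.

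In Sirt6 knockout spleens heterozygous for Rela, most ribosomal protein genes lay above the pool and most matrix genes below it, though neither list passed camera with an estimated correlation (adjusted p = 0.605 for both). Ribosomal protein genes had a median of 0.99, with 50 of 55 above the pool, 30 called higher by limma over the list alone and 6 over all genes. In the knockout group 43 of 55 also lay above the pool, with a median of 0.62. Lying above the pool was thus not particular to the heterozygous group. Rpl41 rose by 2.37 ± 0.28 (SE, n = 3), Rps28 by 2.33 ± 0.30, Rps29 by 2.21 ± 0.26, Rps6 by 2.18 ± 0.27 and Rpl27 by 2.03 ± 0.26. Stromal and matrix genes had a median of -1.01, with 28 of 33 below the pool, 18 called lower over the list alone and 2 over all genes. These 2 were the matrix Gla protein Mgp (-2.70 ± 0.34) and elastin, Eln (-2.28 ± 0.30). The collagen genes Col5a2 (-2.29 ± 0.40) and Col1a1 (-2.23 ± 0.39) passed over the list alone. Camera adjusted p was 5.08e-22 for the ribosomal and 6.32e-11 for the stromal list, against an adjusted p of 0.605 with an estimated correlation for both. Both camera calls held without each array in turn.

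Besides the ribosomal protein genes given above, single genes with the largest changes past the threshold in this group came from varied functions. The zinc finger gene St18 rose by 4.36 ± 0.53 (SE, n = 3), the matrix protease gene Mmp3 by 3.19 ± 0.41 and the chaperone gene Hspa8 by 2.48 ± 0.30. The Y-linked genes Uty and Kdm5d rose by 2.62 ± 0.27 and 2.19 ± 0.25, and they lay above the pool by a like amount on the knockout arrays. The lowest were the proteoglycan gene Ogn (-5.39 ± 0.52), the small heat shock gene Hspb7 (-4.44 ± 0.57), the glutamate receptor gene Grik1 (-3.77 ± 0.47), Lrrn4 (-3.46 ± 0.41), Ecrg4 (-3.36 ± 0.29), the insulin-like growth factor binding protein Igfbp6 (-3.34 ± 0.33), the monooxygenase Fmo2 (-3.28 ± 0.37) and Nrep (-3.24 ± 0.29). In the knockout group St18, Grik1 and Ecrg4 also lay far from the pool the same way (2.87, -3.13 and -2.57). Mmp3, Hspa8, Ogn and Nrep lay the same way but nearer to it (1.32, 0.62, -0.99 and -1.06). Hspb7, Lrrn4 and Igfbp6 lay at -0.14, -0.32 and -0.15, and Fmo2 lay on the other side at 1.965. Limma called 29 of 9000 genes (13 higher, 16 lower), all at an adjusted p of 0.0485. At an unadjusted p under 0.05 there were 1175 genes (455 higher, 720 lower), 685 without the library labelled heterozygous 1 and 758 without either knockout array. All 3 arrays lay on 1 side of the pool for 31.6% of genes. This was above the 25% by chance for independent arrays and below the 49.6% of unchanged spleens simulated against a shared pool. The simulated share follows from a pool taken to vary like a spleen, and a pool that varies less would give a lower one. It therefore does not show that these arrays agree less than unchanged spleens. The count of 29 depended on the setting: it was 53 after quantile normalization (22 higher, 31 lower), 5 with the values as deposited (0 higher, 5 lower), and 0 with arrays scaled to 1 spread or with a robust fit. It was 0 without any 1 of knockout arrays 1 and 2 and heterozygous arrays 1 and 3, and 3 without heterozygous array 2.

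**Figure D2:**
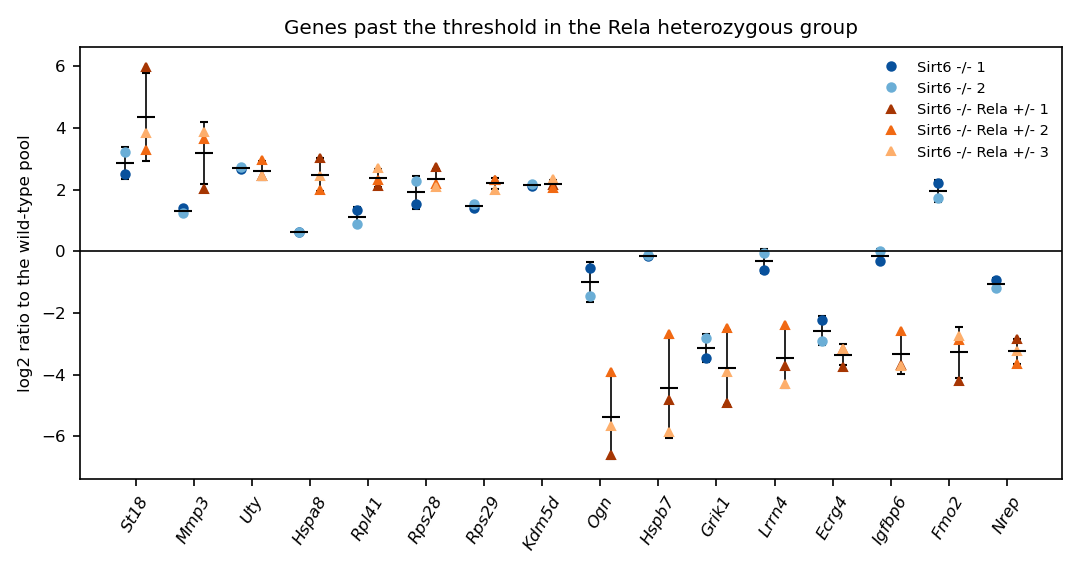
Log2 ratio to the wild-type pool of the 8 genes with the largest rise and the 8 with the largest fall past the threshold in the Sirt6 knockout Rela heterozygous group, for each of the 2 knockout arrays (circles) and 3 heterozygous arrays (triangles), with the group mean (bar) and SD (whiskers). Uty and Kdm5d lay above 2 on all 5 arrays, and Fmo2 lay above the pool on both knockout arrays and below it on the 3 heterozygous arrays.

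Interferon-stimulated genes had a median of 0.43 in this group and B cell markers one of -0.44. Of 32 interferon genes 0 passed over the list alone, with Oas1a at 1.46 ± 0.30 (SE, n = 3) and Ifit1 at 1.39 ± 0.38, and of 21 B cell markers 2 did, Vpreb3 (-1.91 ± 0.28) and Fcrla (-1.63 ± 0.35). Camera called both lists (adjusted p = 0.0170 and 0.0159, and adjusted p = 0.993 with an estimated correlation for both). The first call was lost without heterozygous array 2 (adjusted p = 0.496) and the second without heterozygous array 3 (adjusted p = 0.347). NF-kB target genes had a median of 0.21, with 24 above and 19 below the pool, 0 past the list alone and a camera adjusted p of 0.315. Vcam1 was at 1.20 ± 0.29, Traf1 at 1.62 ± 0.50 and Il1b at 1.22 ± 0.41. Without heterozygous array 3 camera at the preset correlation called this list higher (mean 0.45, adjusted p = 0.00116). With all arrays its camera adjusted p was 0.993 with an estimated correlation. Erythroid genes had a median of -0.12, but their medians of -1.16, -0.68 and 1.41 on heterozygous arrays 1, 2 and 3 lay on both sides of the pool. Cell cycle genes did the same (-1.66, -0.48 and 0.89). Without array 3 camera at the preset correlation called both lists lower in this group (adjusted p = 8.00e-10 and 2.62e-10), and without array 1 it called the erythroid list higher (adjusted p = 0.0255). With all arrays the camera adjusted p with an estimated correlation was 0.998 for the erythroid and 0.993 for the cell cycle list.

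Compared directly, the heterozygous group lay above the knockout group on average in interferon-stimulated, erythroid and cell cycle genes and below it in glucocorticoid-responsive, matrix, growth factor axis and neutrophil genes. The array medians of the groups overlapped for the cell cycle and neutrophil lists. Interferon-stimulated genes differed by a median of 1.17, with all 32 members higher and 8 called over the list alone. Oas1a differed by 3.34 ± 0.47 (SE, n = 3 and 2), Ifit1 by 3.62 ± 0.60, Usp18 by 3.23 ± 0.53 and Oas1g by 3.44 ± 0.67. Glucocorticoid-responsive genes differed by a median of -2.17, with 14 of 22 called lower over the list alone, including Errfi1 (-4.46 ± 0.67), Klf9 (-2.93 ± 0.45), Fam107a (-3.66 ± 0.60) and the transcription factor Cebpd (-4.49 ± 0.80). Their array medians were 1.83 and 1.98 in the knockout group and -0.73, 0.50 and -0.42 in the heterozygous group. Stromal and matrix genes differed by a median of -1.40, with 15 of 33 called lower over the list alone. Lox, which cross-links collagen, differed by -6.04 ± 0.85, Pdgfra by -3.71 ± 0.48, Col4a2 by -1.94 ± 0.43 and the chemokine Cxcl12 by -2.45 ± 0.40. Growth hormone and insulin-like growth factor genes differed by a median of -1.69, with 6 called lower and 1 higher over the list alone. Igfbp3 (-3.15 ± 0.45), Igfbp6 (-3.19 ± 0.52) and Irs1 (-2.27 ± 0.41) were lower and Igfbp2 (3.68 ± 0.73) was higher. Camera adjusted p was 2.22e-14 for the interferon, 1.75e-14 for the glucocorticoid, 8.83e-13 for the stromal and 2.99e-06 for the growth factor list. With an estimated correlation the adjusted p was 0.256 for the interferon, stromal and growth factor lists and 0.437 for the glucocorticoid list. The growth factor list was the only one past fry (fry adjusted p = 0.00766).

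Erythroid genes differed by a median of 2.08, with 8 of 38 called higher over the list alone, and cell cycle genes by 1.38, with all 47 higher and 0 called. The red cell anion exchanger Slc4a1 differed by 4.60 ± 1.07 (SE, n = 3 and 2), Epb42 by 4.83 ± 1.19, Sptb by 3.65 ± 0.81 and the blood group gene Kel by 3.16 ± 0.81. Uhrf1 differed by 2.49 ± 0.56 and Cenpe by 1.75 ± 0.53. On heterozygous array 3 both lists lay above the pool, unlike on the other 4 arrays, and the cell cycle median of the library labelled heterozygous 1 (-1.66) lay beside those of the knockout arrays (-1.63 and -1.97). Pancreatic acinar genes differed by a median of 2.24, with 4 of 12 called, including Ctrb1 (2.58 ± 0.55), Gp2 (5.19 ± 1.38) and Zg16 (2.46 ± 0.66), but their array medians ran from -2.11 on heterozygous array 3 to 1.31 on array 1. Neutrophil and granule genes differed by a median of -1.63, with 3 of 23 called lower, namely Stfa3 (-7.48 ± 1.07), Camp (-3.15 ± 0.54) and Chil3 (-3.63 ± 0.89). Their array medians were 1.79 and 0.60 in the knockout group and -1.24, 1.03 and -0.76 in the heterozygous group, so heterozygous array 2 lay above knockout array 2. Camera called these 4 lists (adjusted p = 7.31e-19, 2.11e-13, 3.31e-07 and 9.26e-07), with adjusted p = 0.576 with an estimated correlation for each. The neutrophil call was lost with heterozygous arrays 1 and 3 both left out, a setting added after the data were seen that leaves 1 heterozygous array.

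Natural killer cell markers differed by a median of 0.96 (Klre1 by 3.14 ± 0.61, SE, n = 3 and 2, the 1 member past the list alone), ribosomal proteins by 0.53 and unfolded protein response and heat shock genes by 0.94 (Hsp90aa1 by 2.10 ± 0.63, Hsp90b1 by 1.84 ± 0.63). Of the last 2 lists 0 members passed over the list alone. Camera adjusted p was 0.000183, 6.74e-07 and 0.000200 for these lists, and the adjusted p with an estimated correlation was 0.576, 0.576 and 0.256. The array medians of the groups overlapped for natural killer genes (-0.54 and -1.11 in the knockout, 0.29, 0.48 and -0.665 in the heterozygous group). They also overlapped for ribosomal proteins (0.89 and 0.43 against 0.63, 1.49 and 1.08). A further 7 lists passed camera and lost the call without 1 or more arrays. Core histones (median 1.01, adjusted p = 2.93e-05), immediate early genes (-0.88, 0.00225), endothelial genes (-0.65, 0.00263) and B cell markers (0.40, 0.00197) lost it without knockout array 2, with adjusted p = 0.128, 0.162, 0.0883 and 0.0565. B cell markers also lost it without heterozygous array 1 (0.0555). Oxidative phosphorylation (median 0.45, adjusted p = 0.000694) lost it without knockout array 2 (0.0670) or heterozygous array 3 (0.0735). DNA repair (0.16, 0.0327) lost it without knockout array 1 (0.112) or heterozygous array 3 (0.188), and macrophage markers (-0.71, 0.0129) without knockout array 1 (0.348) or heterozygous array 1 (0.0794) or 3 (0.143). With an estimated correlation the adjusted p was 0.706 for the oxidative phosphorylation and macrophage lists and 0.576 for the other 5. Dusp1, 1 of the immediate early genes, differed by -2.76 ± 0.52.

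NF-kB target genes, the list named for the factor that Rela encodes, showed no shift between the groups past the test. Of 43 members 21 were higher and 22 lower in the heterozygous group, with a median difference of -0.02, 0 past the list alone and a camera adjusted p of 0.481. The mean of members was -0.12, and 0.21 without heterozygous array 3, where camera did not call the list either (adjusted p = 0.207). The members with the largest statistics were Nfkbib (-2.21 ± 0.43, SE, n = 3 and 2), Tnfaip2 (1.85 ± 0.51), Vcam1 (-1.53 ± 0.45) and Ier3 (-1.82 ± 0.54).

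Gene by gene, limma called 0 of 9000 genes between the mutant groups, with a smallest adjusted p of 0.204. At an unadjusted p under 0.05 there were 794 genes (313 higher, 481 lower in the heterozygous group), against 450 by chance. Arrays of the groups did not overlap for 28.2% of genes, against 20% by chance. Besides members of the interferon list, the non-overlapping genes with the smallest p included a further interferon-inducible gene, Ifi27l2a (3.39 ± 0.59, SE, n = 3 and 2), the myeloid receptor Cd300ld (3.69 ± 0.53), the claudin Cldn10 (4.05 ± 0.71), Abhd2 (2.55 ± 0.48) and the spindle gene Spag5 (2.65 ± 0.50). On the lower side were Fmo2 (-5.24 ± 0.58), the glypican Gpc3 (-3.73 ± 0.42), the cell cycle inhibitor Cdkn1c (-3.49 ± 0.48) and the transcription factor Klf15 (-3.18 ± 0.45). None of these passed, with adjusted p between 0.204 and 0.243. The count was 135 with the least variable 25% of genes left out. The unadjusted count was 328 without knockout array 1, 269 without knockout array 2 and 1385 without the library labelled heterozygous 1. Leaving out that library and heterozygous array 3 together, a setting added after the data were seen, leaves 1 heterozygous array. The spread then comes from the 2 knockout arrays alone. The counts for that setting, listed with the other settings below, therefore decide nothing about the groups.

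Genes picked as far from the pool on 1 knockout array had medians nearer to it on the Rela heterozygous arrays than on the other knockout array. The 450 highest genes on knockout array 1 had a median of 1.77 on knockout array 2 and a mean of medians of 0.30 ± 0.59 (SD, n = 3) on the heterozygous arrays. The 450 lowest had a median of -2.30 on knockout array 2 and -0.55 ± 0.93 on the heterozygous arrays. Picked on knockout array 2 and read on array 1, the highest had a median of 1.53 against 0.45 ± 0.69, and the lowest one of -1.95 against -0.82 ± 0.89. The size of the gap differed between heterozygous arrays. For the lowest genes picked on knockout array 2, the library labelled heterozygous 1 had a median of -1.69, array 2 one of -0.85 and array 3 one of 0.09. No test was made, since picking on 1 knockout array leaves 1 to read. A group whose differences from the pool are unrelated to those of the knockout would also lie nearer to the pool in these genes. The gap alone therefore does not show a return to wild type.

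**Figure D3:**
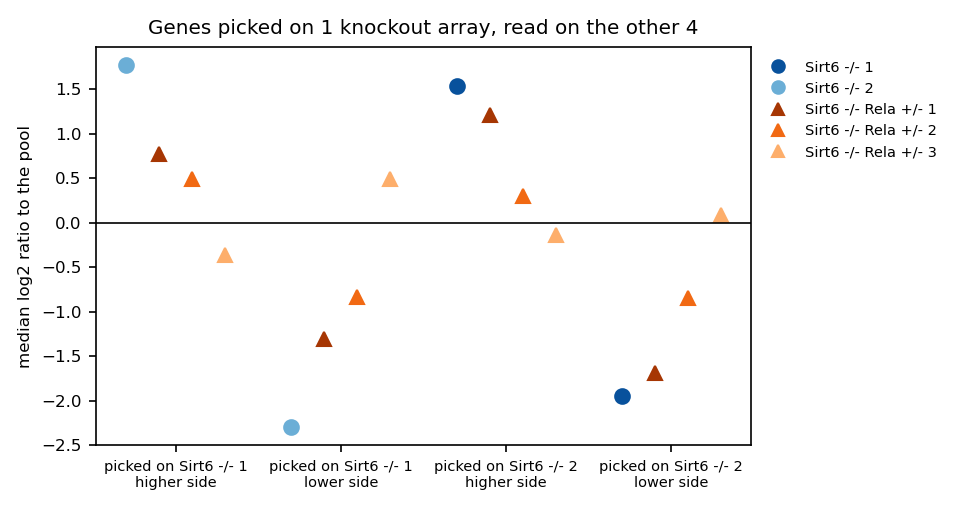
Median log2 ratio to the wild-type pool of the 450 highest and 450 lowest genes picked on 1 Sirt6 knockout array, read on the other knockout array (circles) and on the 3 Sirt6 knockout Rela heterozygous arrays (triangles). In each of the 4 picks the heterozygous arrays sat on the pool's side of the knockout array that was read, from the library labelled heterozygous 1, the nearest to it, to array 3 on the other side of the pool.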

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

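These lists met a rule set before the data were examined: they lay on opposite sides of the pool in the knockout and the heterozygous groups on every array. The tests of the explanations weighed after them were chosen after seeing the result, except those of the Rela probe and of islet genes, which were written before. The growth hormone and insulin-like growth factor list had array medians of 0.83 and 1.31 in the knockout group and -0.67, -0.46 and -0.65 in the heterozygous group, a difference of -1.69 (camera adjusted p = 2.99e-06, and adjusted p = 0.256 with an estimated correlation). Stromal and matrix genes had medians of 0.26 and 0.17 against -1.04, -0.61 and -1.27, a difference of -1.40 (camera adjusted p = 8.83e-13, and adjusted p = 0.256 with an estimated correlation). Unfolded protein response and heat shock genes had medians of -0.61 and -0.61 against 0.31, 0.14 and 0.36, a difference of 0.94 (camera adjusted p = 0.000200, and adjusted p = 0.256 with an estimated correlation).

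Erythroid genes had a median of 1.41 and cell cycle genes one of 0.89 on heterozygous array 3, while both lay below the pool on the other 4 arrays. Dyes reversed on that array are argued against by the Y-linked genes, the lowest of which lay at 2.02 there, above the pool as on the other arrays. An unusual pool alone is argued against by the range of the erythroid medians, 3.72, which was 2.35 times the widest interquartile range of members on an array (1.58). Different shares of erythroid cells in the spleens stay open: 37 of 38 erythroid members (97.4%) were highest on array 3, but the list was singled out for being high there, so this share decides nothing. Cell counts are not given in the sources used here.

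The library labelled heterozygous 1 had Rela at 1.15, the level of the knockout arrays, and a covariance of 0.846 with knockout array 2, and the split that sets it with the knockout arrays gave the most genes of the 10 (1272 against 794). A knockout spleen under a wrong label is argued against by the 100 genes that best separate the knockout arrays from the other 2 heterozygous arrays, where on a scale from 0 (heterozygous) to 1 (knockout) it lay at 0.345 (0.269 to 0.427 over 10000 draws of genes, not of samples). Left out in turn and read the same way, the knockout arrays lay at 0.873 and 0.870 and heterozygous arrays 2 and 3 at 0.491 and -0.050. Noise of the single Rela probe is allowed by its distance of 1.29 from the other heterozygous arrays, at percentile 75.7 of genes with 1 probe (median 0.735). The Rela genotype itself stays open, and 5 arrays do not give the spread of such positions between samples.

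Pancreatic acinar genes had medians of -2.57 and -2.80 on the knockout arrays and of 1.31, -0.28 and -2.11 on the heterozygous arrays. The difference of 3.77 between heterozygous array 1 and the knockout mean (random lists of the same size -0.695 to 0.566) decides nothing about a general tendency of that array, since the arrays were centred and the list was singled out for it. Pancreatic tissue carried with some spleens or with the pool stays open: of the islet genes with a value on the 3 arrays compared, 100% were higher on heterozygous array 1, but this was 1 gene. That gene, Ttr, does not follow the acinar genes elsewhere, with 2.17 on heterozygous array 3 and -3.60 on array 2. No biological explanation was tested for the acinar genes.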

How the results depend on the processing

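The limit common to all comparisons is the number of arrays, 2 and 3. Leaving out heterozygous arrays 1 and 3 together was chosen after seeing the data. It leaves 1 heterozygous array, so the spread comes from the 2 knockout arrays alone. Its counts of genes and lists are therefore not comparable with those of the other settings, and nothing is concluded from them. The count of genes past limma in the heterozygous group against the pool, 29, became 5 with values as deposited (0 higher, 5 lower), 53 after quantile normalization (22 and 31), and 301 with the least variable 25% of genes left out (71 and 230). It became 0 with scaling to the same median absolute deviation, genes with at least 2 arrays per group, each probe on its own, only the arrays of the group, or robust eBayes. Without each array in turn it ran from 0 to 3. In the knockout group the count of 0 became 641 with the least variable 25% left out (219 and 422) and 3321 with only its own arrays (1564 and 1757), and stayed at 0 without each array in turn. In the difference the count of 0 became 135 with the least variable 25% left out (54 and 81), and stayed at 0 without each array in turn. Leaving out the least variable genes removes genes from the adjustment and changes the estimate of spread. With only the arrays of the group, the unadjusted count was 4323 in the knockout and 758 in the heterozygous group. Without each array in turn it ran from 446 to 2634 in the knockout group, from 685 to 1616 in the heterozygous group and from 269 to 1385 in the difference. Without heterozygous arrays 1 and 3 together, limma called 354 genes in the heterozygous group (189 and 165) and 436 in the difference (173 and 263, unadjusted 1813), and camera called 24 lists in the heterozygous group (16 and 8). The number of lists past the test was 0, 0 and 0 with an estimated correlation and 1, 0 and 1 with fry, against 17, 4 and 18 with camera. Without each array in turn it ran from 15 to 17, from 4 to 13 and from 13 to 21. For attenuation, the gap between knockout and heterozygous arrays was 2.23 with the 1% highest genes on knockout array 1, against 1.47 with 5%.

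The direction turned in these cases. With each probe on its own in the knockout group, a probe of Mbd2 read 0.17 and a probe of Cxcl12 -0.11. Rela in the heterozygous group ran from -0.14 to 0.53 without each array in turn, and was -0.084 without heterozygous arrays 1 and 3, where Slc4a1 was -0.35. For lists the direction of the test turned at least once without each array in turn, with these ranges of the mean of members. In the knockout group they were adipose -0.66 to -0.60, inflammatory -0.062 to 0.30, megakaryocyte -0.45 to 0.13 and T cell -0.029 to 0.22. In the heterozygous group they were cell cycle -1.08 to 0.19, cholesterol -0.15 to 0.0086, endothelial -0.078 to 0.36, erythroid -0.98 to 0.43, glycolysis -0.34 to 0.062, progenitor -0.14 to 0.38, hypoxia -0.045 to 0.093, inflammatory -0.62 to 0.15, macrophage -0.36 to 0.37, mast cell -0.28 to 0.94, megakaryocyte -1.22 to 0.099, neutrophil -0.94 to 0.12, NF-kB -0.074 to 0.45, natural killer -0.23 to 0.80, oxidative phosphorylation -0.10 to 0.40, acinar -1.24 to 0.43, plasma cell -0.65 to 0.90, senescence -0.011 to 0.28, muscle -0.27 to -0.032 and T cell -0.38 to 0.46. In the difference they were adipose -0.39 to 0.12, inflammatory -0.74 to 0.035, mast cell -0.75 to 0.46, megakaryocyte -1.06 to 0.26, MHC class II -0.028 to 0.88, NF-kB -0.32 to 0.21, p53 -0.12 to 0.035 and T cell -0.48 to 0.36. Without heterozygous arrays 1 and 3, means whose test turned were cholesterol 0.057, glucocorticoid 0.43, hypoxia -0.11, inflammatory 0.75, megakaryocyte 1.38, neutrophil 1.01, plasma cell 1.51 and muscle 0.15 in the heterozygous group. In the difference they were inflammatory 0.63, macrophage 0.35, mast cell 1.41, megakaryocyte 1.54, NF-kB 0.27 and T cell 0.52. With fry the test of T cell markers in the heterozygous group turned (mean -0.048). The cause was not tested for any of these changes. In the other settings run, apart from the replicate block described next, genes and lists kept their direction. Lists were run only with values as deposited, an estimated correlation, fry, the block and arrays left out.

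With the replicate number as a block, limma called 42 genes in the difference (20 higher, 22 lower, unadjusted 518), and camera gained 3 lists and lost 4 (DNA repair, endothelial, macrophage and oxidative phosphorylation). The test turned for progenitor 0.010, inflammatory 0.035, mast cell 0.46, megakaryocyte 0.22, NF-kB 0.21, p53 0.014 and T cell 0.36 (means of members). The cause was not tested. The labels give the numbers no meaning beyond naming samples. Deviations of same-numbered arrays correlated at -0.409 and -0.399. With 2 knockout arrays these values mirror those of differently numbered arrays (0.399 and 0.409), so they decide nothing about pairing. Number 3 occurs in 1 group, so the block takes heterozygous array 3 out of the difference. No paired analysis was possible against the pool because the pool has no replicates.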

Other observations

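Only the test of other splits belongs to this part, and it was chosen before seeing the result. None of the genes of fat tissue, metabolism, hypoxia and senescence named next passed limma over all genes in these comparisons. Adiponectin, Adipoq, lay below the pool on all 5 arrays (-3.47 ± 0.59, SE, n = 2, in the knockout and -3.31 ± 0.48, n = 3, in the heterozygous group), and carbonic anhydrase Car3 was at -2.98 ± 0.54 in the knockout group, where 4 of 9 adipose genes lay above the pool and 5 below. The kinase Pdk4, which restrains glucose oxidation, was at 2.43 ± 0.64 in the knockout group and differed by -4.41 ± 0.82 between the groups, and the glycolytic enzyme gene Pfkm was at -1.68 ± 0.34 in the knockout group. Medians in the knockout, the heterozygous group and the difference were -0.08, -0.59 and -0.31 for adipose genes (camera adjusted p = 0.770, 0.269 and 0.545) and 0.51, 0.15 and -0.32 for glycolysis (0.0968, 0.673 and 0.214), where the mean in the heterozygous group was -0.10. Hypoxia targets had medians of 0.63, 0.10 and -0.43 (0.134, 0.963 and 0.160), with Vegfa at 2.38 ± 0.64, Ddit4 at 2.05 ± 0.46 and Mxi1 at -2.56 ± 0.47 in the knockout group. Senescence-associated genes had medians of 0.92, 0.16 and -0.20 (0.134, 0.770 and 0.481), with the cell cycle inhibitor Cdkn2b at -1.58 ± 0.43 and Igfbp3 at 1.58 ± 0.35 in the knockout group.

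None of the cytokine and dendritic cell genes named next passed limma over all genes either. Interferon gamma, Ifng, lay below the pool on all 5 arrays (-3.15 ± 0.48, SE, n = 2, and -2.10 ± 0.39, n = 3), as did the plasmacytoid dendritic cell gene Siglech (-1.76 ± 0.44 and -2.15 ± 0.36). Inflammatory cytokine and chemokine genes had medians of 0.10, -0.18 and 0.15 (camera adjusted p = 0.770, 0.349 and 0.336), with a mean of -0.28 in the difference, and Ccl22 was at -2.39 ± 0.47 in the knockout group. Dendritic cell markers had medians of 0.25, 0.56 and 0.17 (0.705, 0.269 and 0.101), with a mean of -0.20 in the knockout group. The other lists were MHC class II (0.12, 0.85 and 0.37, adjusted p = 0.770, 0.210 and 0.283), plasma cell (-0.76, -0.51 and 0.46, adjusted p = 0.199, 0.961 and 0.216, mean 0.07 in the heterozygous group), megakaryocyte (-0.07, -0.38 and -0.10, adjusted p = 0.770, 0.523 and 0.668), mast cell (0.70, 0.41 and -0.39, adjusted p = 0.199, 0.277 and 0.660), haematopoietic progenitor (0.64, 0.11 and -0.56, adjusted p = 0.199, 0.770 and 0.283), cholesterol and fatty acid synthesis (-0.32, -0.07 and 0.21, adjusted p = 0.507, 0.993 and 0.481), skeletal muscle (-0.25, 0.06 and 0.13, adjusted p = 0.770, 0.985 and 0.667, mean -0.13 in the heterozygous group) and p53 target genes (0.13, 0.10 and -0.09, adjusted p = 0.705, 0.770 and 0.696), all by camera. Stromal genes had a median of 0.35 in the knockout group (camera adjusted p = 0.107), with 5 called higher and 2 lower over the list alone. T cell markers had medians of -0.01 and 0.04 in the heterozygous group and the difference (camera adjusted p = 0.993 and 0.696), with a mean of -0.14 in the difference, where the test pointed lower.

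Camera called several lists only once an array was left out, besides the NF-kB, erythroid and cell cycle calls given above. All these calls used the preset correlation, and with all arrays 0 lists passed with an estimated correlation in any comparison. Without heterozygous array 3 the further lists were, in the heterozygous group, MHC class II (adjusted p = 0.00567), dendritic cell (0.0326), T cell (0.00513) and natural killer cell markers (0.00735), immediate early genes (0.0404), core histones (0.0107) and DNA repair (0.00720). In the difference they were MHC class II (0.00334), dendritic cell (0.00192), plasma cell (0.000159) and T cell markers (0.0152, there higher). Without heterozygous array 2 they were megakaryocyte (1.14e-05), neutrophil (0.0121), glucocorticoid-responsive (0.0341) and inflammatory genes (0.0179) in the heterozygous group, and megakaryocyte (0.000135), inflammatory (0.0257) and glycolysis genes (0.0438) in the difference. Without the library labelled heterozygous 1 they were oxidative phosphorylation (8.42e-06), acinar (5.99e-05), adipose (0.00851), growth factor axis (0.0198) and heat shock genes (0.0409) in the heterozygous group, and hypoxia targets (0.0465) in the difference.

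The Y-linked genes Uty (2.44 to 2.96), Kdm5d (2.07 to 2.34) and Eif2s3y (1.45 to 2.78) lay above the pool on all 5 arrays. The sex of the animals and of the pool is not given in the sources used here. Read as ratios of mutant over pool, these values put more Y-linked transcript in every mutant spleen than in the pool. A difference in sex between spleens and pool therefore cannot be told apart from genotype in the comparisons with the pool. In all, 1897 genes (21.1%) lay on 1 side of the pool on all 5 arrays, above the 6.25% by chance for independent arrays. The share was below the 32.6% of unchanged spleens simulated against a shared pool, a figure that follows from the spread assumed for the pool. Of these 1897 genes, 59 lay more than 1 from the pool on every array (26 higher, 33 lower). The 26 higher ones included ribosomal protein genes such as Rps28, Rps29, Rps6 and Rpl27. Every array shares the pool and the dye orientation, so what sets the pool apart stands in these genes too.

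Of the 10 splits of the 5 arrays into 2 and 3, 4 gave as many genes at an unadjusted p under 0.05 as the split by genotype (794), itself included. The highest was 1272, with heterozygous arrays 2 and 3 apart from the rest, followed by 1102 for heterozygous arrays 1 and 3 and 818 for knockout array 2 with heterozygous array 1. With 10 splits no share under 0.05 could arise. The count of 794 thus does not single out the split by genotype.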
